A study of Mus musculus with 24 samples.

How the data were processed

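Messenger RNA was measured in whole hearts of 24 adult C57BL/6J mice of 4 genotypes. Wild-type mice (WT), mice with a cardiac transgene for OGA (OGA_TG), mice with a cardiac transgene for OGT (OGT_TG) and mice with both transgenes (DTG) were each represented by 6 hearts, 3 from males and 3 from females. OGT is the enzyme that adds O-linked N-acetylglucosamine (O-GlcNAc) to proteins, and OGA is the enzyme that removes it. Per the labels, whole hearts were homogenised in Trizol, polyadenylated RNA was made into stranded libraries, and these were sequenced as 100 bp paired-end reads on a NovaSeq.

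The authors deposited 1 table of FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of a library) for all 24 libraries on the mouse genome build mm10. Their processing notes name FastQC for read quality, TopHat for alignment, SAMtools, StringTie for assembly and Cuffdiff 2.2.1 for quantification. The table had 19664 rows. Of these, 4 rows with missing values were left out, 1 of which had no value in any library. Another 343 rows joined several gene symbols into 1 locus, 328 of them above the expression minimum. The latter were tested but were left out of the gene lists. No row of the table was a mitochondrially encoded gene. Gene positions came from the GENCODE M21 annotation on the same build, matched by symbol. Rows named OGT and OGA in capitals were taken as the transgene rows from their names and values, and the mouse genes were the rows Ogt and Mgea5, the older symbol of Oga.

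The deposited unit, FPKM, holds no counts, so the depth of a library is not stated. FPKM values near the bottom of the scale differ by whole fragments. Ratios between libraries over rows with a mean under 0.3 FPKM were used to estimate relative depth. Between 45.7% and 60.1% of these ratios lay at a ratio of small whole numbers, against at most 2.25% in windows moved off such ratios. The scale in fragments was then set with 257 rows named for a gene with a single transcript of over 3000 bases. The estimated depth ran from 11.3 to 17.6 M fragments per library. The sum of FPKM per library ran from 463500 to 513602. The 50 most abundant rows held 27.1% to 32.5% of it.

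Rows with an FPKM of at least 1 in at least 6 libraries were tested, which kept 12020 of 19660 rows. Differences were tested with limma 3.58.1 (moderated two-sided test with an intensity trend) in R 4.3.3 on log2(FPKM + 1), with 4 groups and sex as terms and all 24 libraries in 1 model. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested rows. The comparisons were each transgenic genotype against WT, DTG against each single transgenic genotype, OGT_TG against OGA_TG, and the interaction, which is the DTG minus OGT_TG difference less the OGA_TG minus WT difference. A positive interaction means that the difference between hearts with and without the OGA transgene was more positive where the OGT transgene was present. P-values measure the spread between hearts of different mice. In simulated data with the same spread of each row and independent noise between rows, 200 of 12020 rows were changed. The test recovered 74.3% of changes of 0.5 log2 and 96.3% of changes of 1 log2, with 5.00% false calls. Noise shared by genes within a heart was not simulated, so these shares need not hold in the real hearts. The 2 target genes and 2 transgene rows were also compared by exact two-sided permutation tests over all 924 splits of 12 hearts, for which 0.00216 is the smallest p.

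Before the data were examined, 44 gene lists (pathways, complexes and cell type markers, 933 members), the comparisons, the tests, the alternatives and the rule for named genes were fixed. Rows were found for 862 members by symbol, and 774 members passed the expression minimum. Lists with at least 5 tested rows, 35 in all, were tested with camera in limma. It was run with a preset correlation of 0.01 and again with a correlation estimated from each list, and fry was run beside it. List p-values were adjusted over lists within a comparison. List counts are also given adjusted over the list alone. The rule named Ogt and Oga, the 10 largest rises and 10 largest falls per comparison, and up to 4 called members of each list. The largest changes were taken among called genes in which all 6 hearts of one group lay beyond all 6 of the other, with a mean of at least 2 FPKM in a group and no predicted genes. Members of a described list were also allowed.

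Other settings were also run, namely a pseudocount of 0.1, no filter, a stricter filter of 5 FPKM, no sex term, library weights, robust moderation, an adjusted p of 0.01, a fold change minimum, single-sex fits, fits of only the groups compared, the number in the sample titles as a block for WT and OGT_TG, and each heart left out in turn. Values were also rescaled to an equal sum of FPKM per library, by median-of-ratios factors, and by quantile normalization. After the values were seen, 1 alternative was added, which left out OGT_TG replicates 3 and 6. The number that opens the sample titles is shared by WT and OGT_TG mice but not by OGA_TG or DTG mice, and the labels do not say what it stands for. It cannot be told apart from genotype for OGA_TG and DTG. Correlations of differences that share the WT hearts were set beside values from 100 simulated draws of unchanged groups and from WT hearts split between the differences. Counts of genes between groups were compared with counts from 100 splits of the same hearts, the interaction count with 100 reassignments of residuals, and counts of a different effect by sex with 100 reassignments of sex within genotype. Calculations outside R used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots used matplotlib 3.10.9.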

Results

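Gene expression was measured as FPKM in 24 whole mouse hearts, 6 each from WT, OGA_TG, OGT_TG and DTG mice, with 3 males and 3 females per genotype. Estimated depth averaged 14.1 M fragments in WT, 13.3 M in OGA_TG, 14.5 M in OGT_TG and 13.3 M in DTG libraries. Between 11421 and 12141 rows reached 1 FPKM in a heart. Genes of the Y chromosome and Xist, the RNA that silences an X chromosome in females, separated the sexes in each genotype. In the fit of all hearts, Ddx3y was higher in males by 4.57 and Xist lower in males by -4.41 on the log2 scale. Replicates 3 and 6 of OGT_TG stood apart from the other OGT_TG hearts. On the first principal component, which held 40.8% of the variance, they scored 52.7 and 52.9. The other OGT_TG hearts scored from 11.4 to 17.9 and WT hearts from -15.6 to -9.21. For comparisons with OGT_TG, some values are therefore also given without both hearts, an alternative chosen after these scores were seen. A value given only with all hearts may still depend on them. The number that opens the sample titles cannot be told apart from genotype for OGA_TG and DTG, so no value within a shared number can be given for them.

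The first question was whether the transgenes were expressed and whether the mouse genes for the same enzymes moved with them. The OGT row rose from 1.68 ± 1.45 FPKM in WT to 1748 ± 737 FPKM in OGT_TG and 4652 ± 449 FPKM in DTG (SD, n = 6 each). It was higher in DTG than in OGT_TG by 1.54 log2 (SE 0.30, limma adjusted p = 0.00061), and all 6 DTG hearts lay above all 6 OGT_TG hearts. The OGA row was 0.00637 ± 0.0101 FPKM in WT, 4122 ± 732 FPKM in OGA_TG and 3462 ± 294 FPKM in DTG (SD, n = 6). It differed by -0.24 log2 between DTG and OGA_TG, a call with limma (adjusted p = 0.038) that the exact permutation test did not share (p = 0.0736, adjusted 0.0883 over 24 such tests). In OGT_TG replicates 3 and 6 the OGT row stood at 1104 and 714.7 FPKM, below the 1691 to 2691 FPKM of the other 4 OGT_TG hearts.

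Mouse Mgea5, which encodes OGA, fell in OGA_TG hearts to 24.7 ± 3.44 FPKM from 42.0 ± 5.24 in WT (SD, n = 6), a log2 difference of -0.75 (SE 0.12, adjusted p = 0.0017). In OGT_TG it stood at 54.7 ± 10.9 FPKM, 0.36 log2 above WT (adjusted p = 0.019). That call was lost under median-of-ratios scaling (adjusted p = 0.066), under quantile normalization (adjusted p = 0.057), and without WT replicate 2 or OGT_TG replicate 5. Without OGT_TG replicates 3 and 6 the difference was 0.55, and the exact permutation test over all hearts gave p = 0.0411, adjusted 0.0519. Mouse Ogt fell in DTG to 25.5 ± 2.59 FPKM from 35.8 ± 3.24 in WT (SD, n = 6), by -0.48 log2 (adjusted p = 0.00011). Its difference was -0.17 log2 in OGT_TG (adjusted p = 0.066), which became a call at -0.25 under median-of-ratios scaling, at -0.24 under quantile normalization, and without WT replicate 6 or OGT_TG replicate 5. The exact permutation test gave p = 0.0325, adjusted 0.0433 over far fewer tests than with limma, so these adjusted values are not directly comparable. In OGA_TG it was 0.21 log2 with all 6 hearts above the WT mean. Before adjustment limma gave p = 0.0083 and the exact permutation test p = 0.013. Adjusted over all tested rows, the limma value did not pass (adjusted p = 0.29). Adjusted over the far fewer permutation tests, the permutation value passed (adjusted 0.0183). The tests themselves therefore did not disagree here. The drop from OGT_TG to DTG of -0.30 log2 (adjusted p = 0.0034) was lost under median-of-ratios scaling (adjusted p = 0.061) and quantile normalization (adjusted p = 0.06).

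**Figure D1:**
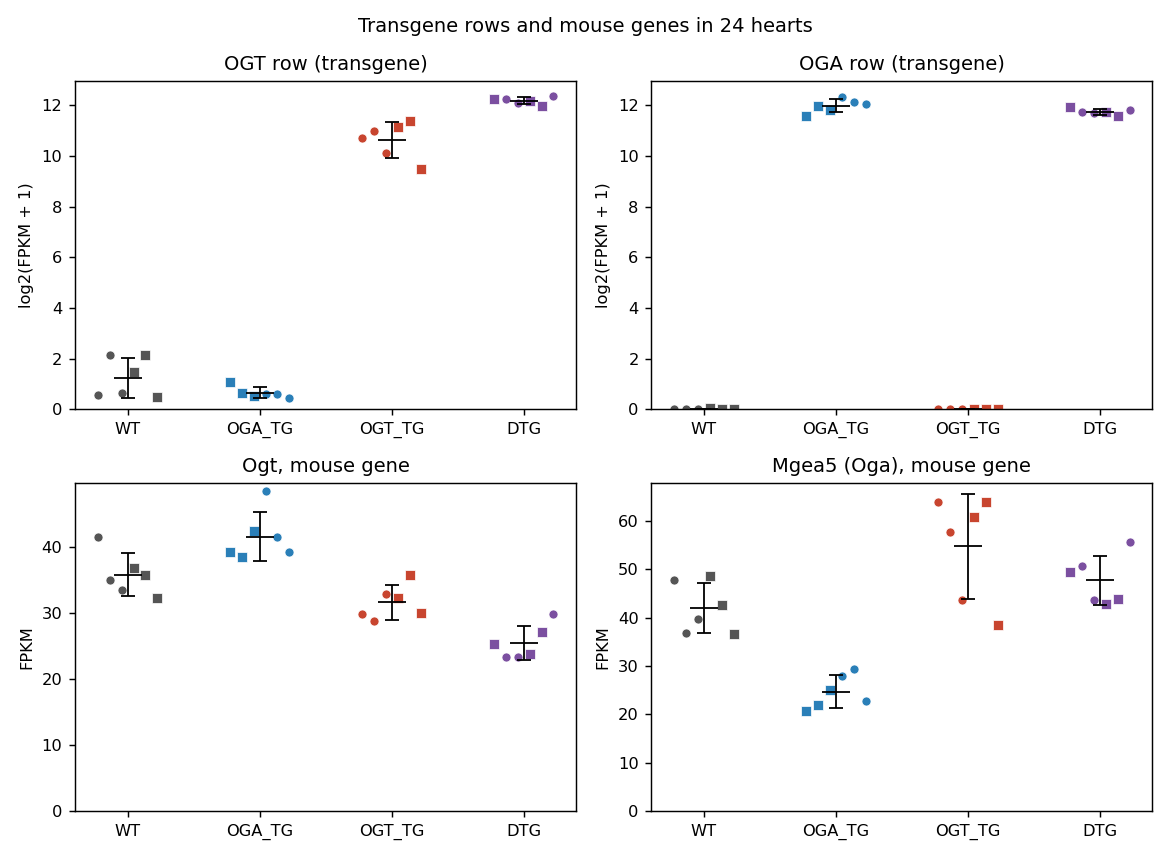
FPKM of the transgene rows, as log2(FPKM + 1), and of the mouse genes Ogt and Mgea5 in each heart by genotype (circles, females, and squares, males), with mean and SD over 6 hearts. Mgea5 averaged 24.7 FPKM in OGA_TG against 42.0 FPKM in WT, and Ogt averaged 25.5 FPKM in DTG against 35.8 FPKM in WT.

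The comparison of OGT_TG with WT asked what excess OGT did to the heart's transcripts. Matrix, fibroblast and most stress genes rose, and most genes of fatty acid oxidation and the respiratory chain fell. These lists passed at the preset correlation, and none passed with an estimated correlation. Cilp, a matrix protein of cartilage and scar, rose from 5.24 ± 0.525 to 69.8 ± 45.7 FPKM (SD, n = 6), and Ankrd1, a stress protein of cardiac muscle, from 886.2 ± 242 to 3823 ± 1401 FPKM. Atp2a2, the pump that returns calcium to the sarcoplasmic reticulum, fell from 4453 ± 234 to 2284 ± 548 FPKM. Ces1d, a lipid esterase, Scn4b, a sodium channel subunit, and Clcn1, a chloride channel, fell by 2.39, 2.18 and 1.77 log2. Of 12020 tested genes, 3029 rose and 1470 fell, 4499 in all, and 288 of them changed by at least 1 log2 (227 rose and 61 fell). All 6 hearts of one genotype lay beyond all 6 of the other for 1817 genes (15.1%), where chance gives 0.2165%.

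All 45 tested genes of the extracellular matrix and fibrosis list rose in OGT_TG, 45 adjusted over the list alone, with a median of 1.27 log2 (camera adjusted p = 5.07e-15). The list's adjusted p = 0.199 with an estimated correlation. Among its members were Timp1 and Timp2, inhibitors of matrix proteases, at 2.64 and 1.06 log2. Mfap5, a microfibril protein from the fibroblast marker list, rose by 1.91 log2. Other large rises were Wisp2 (3.21), Thbs4 (2.97) and Ltbp2 (2.92 log2), which encode secreted matrix proteins. All 13 tested fibroblast markers rose, 13 adjusted over the list alone, with a median of 0.98 log2 (adjusted p = 6.06e-08, and adjusted p = 0.158 with an estimated correlation). Dcn, which encodes the collagen-binding proteoglycan decorin, rose from 374.2 ± 46.6 to 737.2 ± 94.5 FPKM (SD, n = 6). Without OGT_TG replicates 3 and 6, the medians were 0.66 log2 for the matrix list and 0.70 for the fibroblast markers.

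Among 18 tested cardiac stress genes, 12 rose and 1 fell in OGT_TG (12 and 2 adjusted over the list alone), with a median of 1.11 log2 (adjusted p = 9.49e-05, and adjusted p = 0.249 with an estimated correlation). Ankrd1 rose by 2.08 log2 (SE 0.19), and the matrix proteoglycan Bgn by 2.02. The natriuretic peptide genes Nppa and Nppb rose by 1.21 (SE 0.29, adjusted p = 0.0023) and 1.51 log2 (SE 0.29, adjusted p = 0.00039). Nppa reached 10798 and 18112 FPKM in OGT_TG replicates 3 and 6, against 3554 to 4066 in the other 4 hearts. Without both hearts, the rise of Nppa was 0.58 log2 and the list's median 0.53. Atrial cardiomyocyte markers went the other way, with 1 of 11 higher and 6 lower (1 and 7 adjusted over the list alone) and a median of -0.36 log2 (adjusted p = 0.00174, and adjusted p = 0.158 with an estimated correlation). Myl7, the atrial regulatory myosin light chain, fell by 1.14 log2, and by 0.74 without both hearts.

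Of 27 tested fatty acid oxidation genes, 25 fell and 0 rose in OGT_TG, 25 adjusted over the list alone, with a median of -0.61 log2 (adjusted p = 8.24e-18, and adjusted p = 0.158 with an estimated correlation). The mitochondrial enzymes Acadvl, Acaa2 and Hadhb fell by 0.66, 1.16 and 0.80 log2, and Cpt2, which releases imported acyl groups inside mitochondria, by 0.63. In complex I of the respiratory chain, 22 of 35 genes fell (23 adjusted over the list alone), and in complexes II to V 30 of 40 (32 adjusted over the list alone). The medians were -0.27 (adjusted p = 1.29e-12) and -0.32 log2 (adjusted p = 1.76e-15), each with adjusted p = 0.165 with an estimated correlation. Examples were Ndufa3 (-0.52), Cox7a1 (-0.83, and -0.55 without OGT_TG replicates 3 and 6) and Sdha (-0.61 log2, and -0.39 without them). In the tricarboxylic acid (TCA) cycle list, 21 of 26 genes fell (22 adjusted over the list alone), Ogdh among them by 0.47 log2, with a median of -0.35 (adjusted p = 4.53e-14, and adjusted p = 0.165 with an estimated correlation). With both hearts left out the medians were -0.42 for fatty acid oxidation, -0.18 for complex I, -0.21 for complexes II to V and -0.21 log2 for the TCA cycle list.

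Glycolysis genes split, with 8 of 25 higher and 7 lower (8 and 7 adjusted over the list alone). Their median was 0.17 log2, their mean 0.01, and camera pointed down (adjusted p = 0.785). The median was -0.02 without OGT_TG replicates 3 and 6. Pfkp, the platelet form of phosphofructokinase, rose by 1.08 log2, and Hk2, a muscle hexokinase, fell by 0.56. Among 20 branched chain amino acid and ketone catabolism genes 11 fell and 1 rose (13 and 1 adjusted over the list alone), with a median of -0.31 log2 (adjusted p = 1.9e-06, and adjusted p = 0.199 with an estimated correlation). Without both hearts that median was -0.12.

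Calcium handling genes went both ways in OGT_TG. Of 25 calcium handling genes, 12 fell and 8 rose (12 and 8 adjusted over the list alone), with a median of -0.19 log2 (adjusted p = 0.00664, and adjusted p = 0.199 with an estimated correlation). Atp2a2 fell by 1.00 log2 (SE 0.12, adjusted p = 1.2e-06), Hrc, a calcium-binding protein of the sarcoplasmic reticulum, by 1.05, and Ryr2, its release channel, by 0.53. Sri, a calcium-binding partner of the release channel, rose by 0.45. Of 33 ion channel genes 16 fell and 3 rose (19 and 3 adjusted over the list alone), with a median of -0.26 (adjusted p = 5.00e-06, and adjusted p = 0.165 with an estimated correlation). Scn4b fell from 20.8 ± 2.61 to 4.15 ± 2.06 FPKM (SD, n = 6), and Kcnip2, a subunit of the transient outward potassium channel, by 1.15 log2. Irx5, a repressor of cardiac potassium channel genes, rose by 0.54. Of 20 sarcomere genes 7 fell and 1 rose, 7 and 1 adjusted over the list alone, Tnnt2 among the former by 0.34 log2. The list's median was -0.14 (adjusted p = 0.00192, and adjusted p = 0.158 with an estimated correlation). Under quantile normalization the calls of the calcium (adjusted p = 0.0621) and sarcomere lists (adjusted p = 0.771) were lost. The medians without OGT_TG replicates 3 and 6 were -0.12 for calcium handling and -0.17 for ion channel genes.

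Genes of the integrated stress response, inflammation and interferon lists rose in OGT_TG as well, while chaperone genes split. In the integrated stress response list 13 of 24 genes rose and 3 fell (16 and 3 adjusted over the list alone), with a median of 0.43 log2 (adjusted p = 0.00113, and adjusted p = 0.165 with an estimated correlation). Mthfd2, a mitochondrial folate enzyme, rose from 1.31 ± 0.35 to 5.63 ± 0.994 FPKM (SD, n = 6), and Asns, asparagine synthetase, by 0.92 log2. The list's median was 0.27 without OGT_TG replicates 3 and 6. Of 30 chaperone genes 8 rose and 7 fell (9 and 8 adjusted over the list alone), among them the cytosolic chaperone Hsp90aa1 (1.04) and the endoplasmic reticulum chaperone Hspa5 (-0.40 log2). Their median of 0.01, with camera pointing down (adjusted p = 0.487), turned to -0.06 under median-of-ratios scaling and -0.01 under quantile normalization. In the inflammation list 17 of 25 rose and 0 fell (18 and 0 adjusted over the list alone), with a median of 0.65 (adjusted p = 4.15e-05, and adjusted p = 0.165 with an estimated correlation). Per heart, the median of this list against the WT mean was 0.98 and 0.96 in OGT_TG replicates 3 and 6, and 0.33 to 0.56 in the others. In the interferon list 19 of 25 rose and 0 fell (20 and 0 adjusted over the list alone), with a median of 0.46 (adjusted p = 1.9e-06, and adjusted p = 0.199 with an estimated correlation). Examples were the complement gene C3 (0.97), Icam1 (0.98), Ifit2 (0.91) and B2m (0.63 log2).

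Of 24 p53 and cell death genes 16 rose and 0 fell (18 and 1 adjusted over the list alone), with a median of 0.38 log2 (adjusted p = 2.54e-05, and adjusted p = 0.158 with an estimated correlation). Per heart, the median of this list against the WT mean was 0.69 and 0.58 in OGT_TG replicates 3 and 6, and 0.24 to 0.43 in the others. Bcl2, an inhibitor of apoptosis, rose by 1.13 log2 (SE 0.10), and Cdkn1a, an inhibitor of cyclin-dependent kinases, by 1.51. Of 25 ubiquitin and autophagy genes 12 rose and 0 fell (13 and 1 adjusted over the list alone), with a median of 0.18 (adjusted p = 0.0125, and adjusted p = 0.165 with an estimated correlation). Lamp1, a lysosomal membrane protein, rose from 229.8 ± 5.51 to 314.9 ± 9.77 FPKM (SD, n = 6), and the autophagy receptor Sqstm1 by 0.58 log2, while the list's median without OGT_TG replicates 3 and 6 was 0.11. Macrophage markers rose in 15 of 20 cases and fell in 0 (17 and 0 adjusted over the list alone), with a median of 0.62 (adjusted p = 0.00192, and adjusted p = 0.423 with an estimated correlation). That median was 0.23 without OGT_TG replicates 3 and 6, and the rise of Lgals3, a macrophage lectin, was 1.64 log2 with and 0.99 without them. Of 13 endothelial markers 2 rose and 0 fell (0 and 0 adjusted over the list alone), with a median of 0.11 (adjusted p = 0.689), 0.00 without those hearts. In the O-GlcNAc and hexosamine list 5 of 13 rose and 0 fell (6 and 1 adjusted over the list alone), among them Gfpt2, a form of the enzyme that starts hexosamine synthesis, by 0.75 log2, with a median of 0.16 (adjusted p = 0.125).

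When OGT_TG replicates 3 and 6 were left out, 2107 genes rose and 929 fell, 3036 in all, of which 2819 were also among the 4499. Scaling moved the split between rises and falls, to 3587 and 1162 with an equal sum of FPKM, 2193 and 2100 under median-of-ratios scaling and 1955 and 2208 under quantile normalization. The median difference of all tested genes was 0.06 log2 as deposited, 0.10 with an equal sum of FPKM and 0.00 under median-of-ratios scaling.

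**Figure D2:**
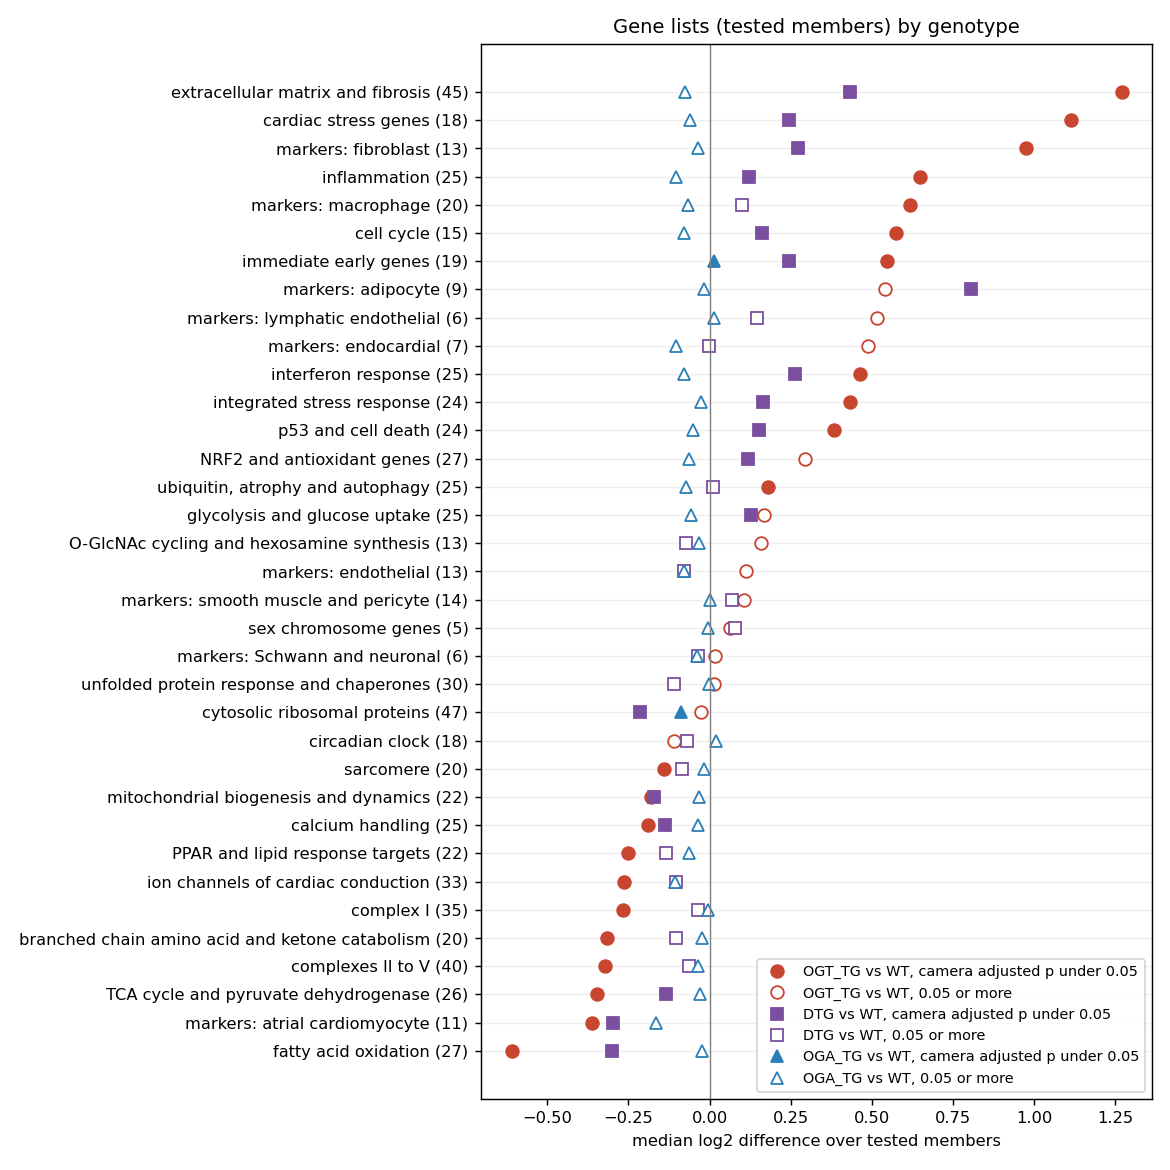
Median log2 difference from WT over the tested members of each gene list (number in brackets) in OGT_TG, DTG and OGA_TG, with filled symbols where camera's adjusted p was under 0.05 at the preset correlation. The extracellular matrix and fibrosis list had medians of 1.27 in OGT_TG and 0.43 in DTG, and fatty acid oxidation had medians of -0.61 and -0.30.

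OGA_TG hearts were compared with WT to see what excess OGA alone did. Tac1, the precursor of substance P, fell from 2.03 ± 0.451 to 0.438 ± 0.28 FPKM (SD, n = 6), and Mal, a myelin and lymphocyte membrane protein, from 9.51 ± 2.05 to 4.20 ± 1.14 FPKM. Igsf1, Camk2b, a subunit of calmodulin-dependent kinase, Epn3, Hsd17b7, an enzyme of cholesterol synthesis, and Cds1, an enzyme of phospholipid synthesis, fell by 0.84, 0.75, 0.76, 0.71 and 0.69 log2. Vmn1r220, a vomeronasal receptor gene on chromosome 13 (23178514 to 23187975, mm10), was listed at 0 FPKM in every WT and OGT_TG heart, at 9.88 ± 1.79 FPKM in OGA_TG and at 6.61 ± 1.17 in DTG (SD, n = 6).

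In OGA_TG 7 genes rose and 36 fell of 12020 tested, and 5 changed by at least 1 log2 (3 rose and 2 fell), among them OGA and Vmn1r220, which rose, and Tac1 and Mal, which fell. Of the list members, Mgea5 alone was called. All 6 hearts lay beyond all 6 WT hearts for 203 genes (1.69%), where chance gives 0.2165%. The cytosolic ribosomal protein list had a median of -0.09 log2 (adjusted p = 0.00821, and adjusted p = 0.999 with an estimated correlation), with 0 of 47 genes called and 0 adjusted over the list alone. Its call was lost with an equal sum of FPKM (adjusted p = 0.0673), median-of-ratios scaling (adjusted p = 0.221) and quantile normalization (adjusted p = 0.095). The split of rises and falls was 10 and 24 with an equal sum of FPKM, 13 and 18 under median-of-ratios scaling, and 9 and 15 under quantile normalization. The count of 43 was 319 with library weights (42 rises and 277 falls), 81 in a fit of OGA_TG and WT alone, 28 without WT replicate 5, 25 without OGA_TG replicate 2 and 23 without OGA_TG replicate 5.

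The comparison of DTG with WT asked what was left when both transgenes were present. Part of the genes of fatty acid oxidation, calcium handling and ribosomal proteins fell, and a smaller set of matrix genes rose. None of these lists passed with an estimated correlation. Hadhb fell from 1381 ± 90.7 to 817.0 ± 40.7 FPKM (SD, n = 6), and Pln, the inhibitor of the sarcoplasmic reticulum calcium pump, from 3336 ± 323 to 1867 ± 148 FPKM. Cilp rose from 5.24 ± 0.525 to 17.4 ± 5.05 FPKM. Of 12020 genes 506 rose and 1372 fell, 1878 in all, and 47 changed by at least 1 log2 (20 rose and 27 fell). All 6 hearts lay beyond all 6 WT hearts for 1125 genes (9.36%), where chance gives 0.2165%.

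The largest rises in DTG included Adamtsl2 (1.78), Wisp2 (1.58), Mfap4 (1.49) and Timp1 (1.34), which encode matrix proteins or their inhibitors, Slc38a1 (1.35), a glutamine transporter, and Alpl (1.19 log2), alkaline phosphatase. Pirt, a regulator of sensory neuron channels, rose from 5.53 ± 1.31 to 13.01 ± 3.19 FPKM (SD, n = 6). Large falls included Ces1d (-1.54), Scgb1c1 (-1.50), Asb5 (-1.38), Scn4b (-1.36), Tmod4 (-1.35), a capper of actin filaments, and Adra1a (-1.28 log2), an alpha-1 adrenergic receptor. As the rule for the largest changes required, all 6 DTG hearts lay beyond all 6 WT hearts in each of these.

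Of 27 fatty acid oxidation genes 15 fell and 0 rose in DTG (16 and 0 adjusted over the list alone), with a median of -0.30 log2 (adjusted p = 7.47e-07, and adjusted p = 0.481 with an estimated correlation). Hadhb and Acadm fell by 0.76 and 0.60 log2, and the lipid uptake genes Lpl and Cd36 by 0.60 and 0.47. In complex I 4 of 35 fell (4 adjusted over the list alone), and the median of -0.04 log2 (adjusted p = 0.922) turned positive, to 0.03, 0.02 and 0.05, under the 3 scalings. In complexes II to V 2 of 40 fell (2 adjusted over the list alone), with a median of -0.06 (adjusted p = 0.375). Of 25 calcium handling genes 10 fell and 0 rose (12 and 0 adjusted over the list alone), with a median of -0.14 (adjusted p = 0.00231, and adjusted p = 0.216 with an estimated correlation). Pln fell by 0.84 log2 (SE 0.15, adjusted p = 0.00049), Atp2a2 by 0.59 and S100a1, a calcium sensor, by 0.34. Of 33 ion channel genes 9 fell and 2 rose (9 and 4 adjusted over the list alone), with a median of -0.10 (adjusted p = 0.29), and Kcnip2 fell by 1.25 log2. Of 26 TCA cycle genes 5 fell and 0 rose (6 and 0 adjusted over the list alone), with a median of -0.13 (adjusted p = 0.00139, and adjusted p = 0.534 with an estimated correlation). Pdk1, a kinase that restrains pyruvate dehydrogenase, fell by 0.55.

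Of 47 cytosolic ribosomal protein genes 24 fell and 0 rose in DTG (30 and 0 adjusted over the list alone), with a median of -0.21 log2 (adjusted p = 6.00e-10, and adjusted p = 0.216 with an estimated correlation). Rpl10 fell from 521.6 ± 38.8 to 396.0 ± 10.2 FPKM (SD, n = 6), and Rpl14 by 0.33 log2. Under the scalings to an equal sum, by median-of-ratios and by quantiles, the median was -0.15, -0.16 and -0.15, and the call held. Of 45 matrix genes 7 rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 0.43 (adjusted p = 2.43e-08, and adjusted p = 0.506 with an estimated correlation). Of 13 fibroblast markers 5 rose and 0 fell (5 and 0 adjusted over the list alone), Gsn, an actin-severing protein, by 0.40, with a median of 0.27 (adjusted p = 1.7e-05, and adjusted p = 0.216 with an estimated correlation). Of 18 stress genes 6 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 0.24 (adjusted p = 0.00706, and adjusted p = 0.534 with an estimated correlation). Nppa and Nppb stood at -0.30 (adjusted p = 0.544) and -0.47 log2 (adjusted p = 0.308) against WT. Of 25 interferon genes 7 rose and 0 fell (11 and 0 adjusted over the list alone), Ifit1 and Irf7 by 0.53 and 0.66, with a median of 0.26 (adjusted p = 6.30e-08, and adjusted p = 0.216 with an estimated correlation). The split of 506 rises and 1372 falls became 754 and 732 with an equal sum of FPKM, 763 and 914 under median-of-ratios scaling and 686 and 885 under quantile normalization.

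**Figure D3:**
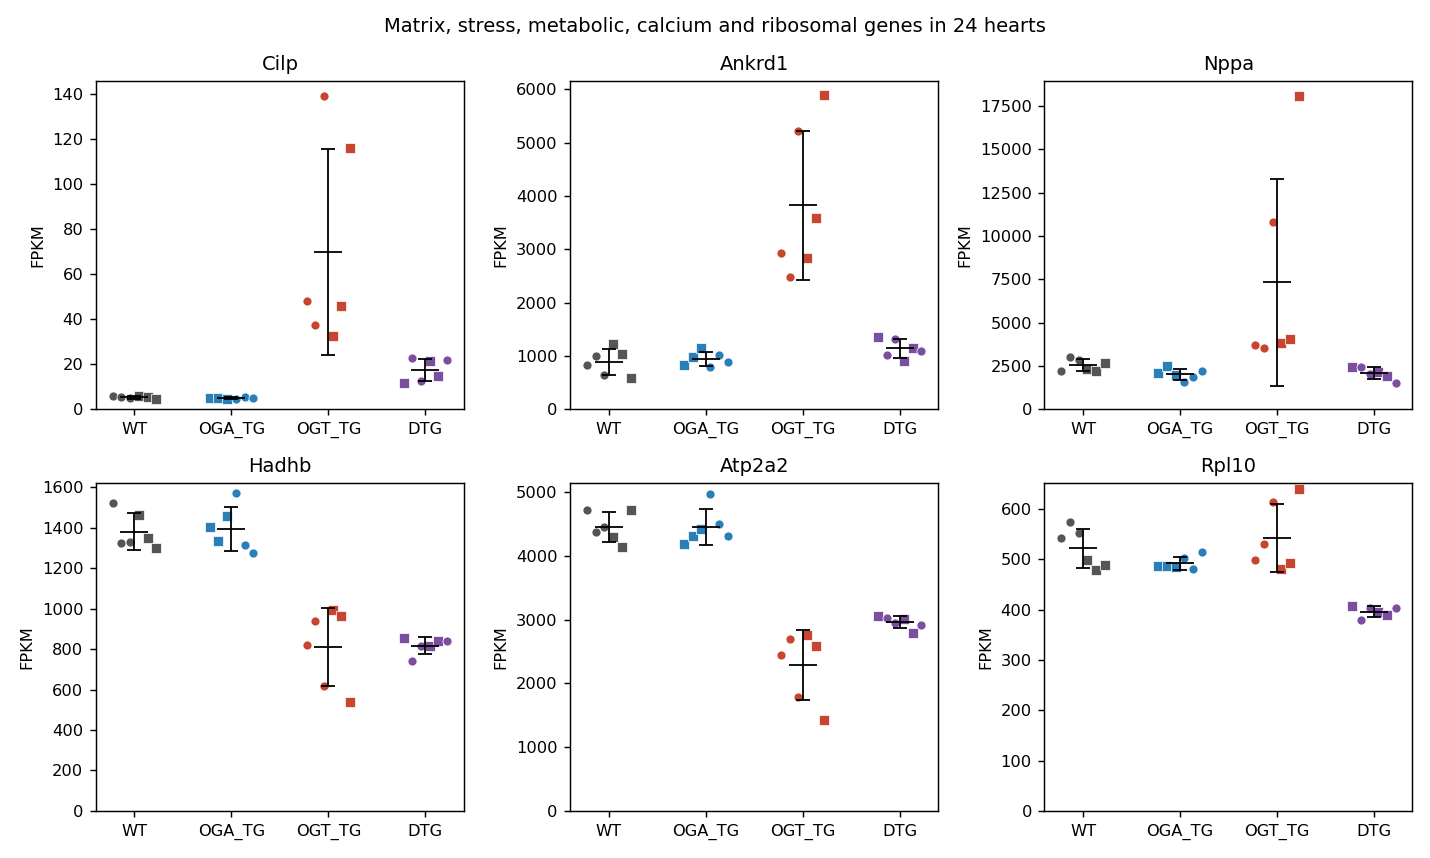
FPKM of 6 genes in each heart by genotype (circles, females, and squares, males), with mean and SD over 6 hearts. Cilp, Ankrd1 and Nppa were highest in OGT_TG replicates 3 and 6, Hadhb averaged 810.7 FPKM in OGT_TG and 817.0 in DTG, and Rpl10 averaged 396.0 FPKM in DTG against 521.6 in WT.

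DTG was compared with OGT_TG to see how hearts with both transgenes differed from hearts with the OGT transgene alone. The OGT row was higher in DTG by 1.54 log2, and the genotypes share no title number. An effect of the OGA transgene cannot be told apart from these differences. Most stress and matrix genes fell, and part of the respiratory chain genes rose. These lists passed at the preset correlation, and none passed with an estimated correlation. Their medians were smaller in size without both OGT_TG hearts that stood apart. Nppb fell from 905.7 ± 557 to 214.6 ± 98.6 FPKM (SD, n = 6) and Ankrd1 from 3823 ± 1401 to 1140 ± 177 FPKM. Kcnj2, the main inward rectifier potassium channel, rose from 10.3 ± 3.79 to 22.5 ± 5.37 FPKM. Of 12020 genes 604 rose and 3274 fell, 3878 in all, and 115 changed by at least 1 log2 (15 rose and 100 fell). All 6 DTG hearts lay beyond all 6 OGT_TG hearts for 1189 genes (9.89%), where chance gives 0.2165%.

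Of 45 matrix genes 30 fell and 0 rose in DTG against OGT_TG (32 and 0 adjusted over the list alone), with a median of -0.88 log2 (adjusted p = 3.25e-07, and adjusted p = 0.444 with an estimated correlation). Comp, Thbs4, Ltbp2, Cilp and Postn, all secreted matrix proteins, fell by 2.32, 2.08, 2.04, 1.76 and 1.78 log2, and Dcn by 0.88. Of 18 stress genes 13 fell and 1 rose (13 and 1 adjusted over the list alone), with a median of -0.90 (adjusted p = 0.00296, and adjusted p = 0.434 with an estimated correlation). Ankrd1 fell by 1.68 log2 (SE 0.19, adjusted p = 4e-06), Nppa by 1.51 and Nppb by 1.98. Of 13 fibroblast markers 10 fell and 0 rose (10 and 0 adjusted over the list alone), with a median of -0.59 (adjusted p = 0.000498, and adjusted p = 0.214 with an estimated correlation). The medians without OGT_TG replicates 3 and 6 were -0.37 for matrix, -0.57 for stress and -0.41 log2 for fibroblast genes. Without both, Comp, Ltbp2, Postn and Nppa fell by 1.28, 1.18, 1.05 and 0.88.

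In complex I 20 of 35 genes rose and 0 fell (25 and 0 adjusted over the list alone), and in complexes II to V 21 of 40 and 0 (27 and 0 adjusted over the list alone). Their medians were 0.24 (adjusted p = 4.78e-19) and 0.25 log2 (adjusted p = 3.00e-20), each with adjusted p = 0.214 with an estimated correlation. Ndufb6 rose by 0.24, by 0.36 under median-of-ratios scaling, and Cox7c by 0.42 log2. Of 27 fatty acid oxidation genes 11 rose and 0 fell (14 and 0 adjusted over the list alone), Cpt2 by 0.49 and Etfb, which carries electrons from fatty acid oxidation, by 0.72, with a median of 0.25 (adjusted p = 3.85e-11, and adjusted p = 0.214 with an estimated correlation). Hadhb stood at 0.05 log2 (adjusted p = 0.782). Leaving out OGT_TG replicates 3 and 6 gave medians of 0.13 for complex I, 0.10 for complexes II to V and 0.07 log2 for fatty acid oxidation. Of 33 ion channel genes 10 rose and 4 fell (11 and 4 adjusted over the list alone), with a median of 0.11 (adjusted p = 2.37e-06, and adjusted p = 0.214 with an estimated correlation), 0.06 without both hearts. Kcnj2 rose by 1.11 and the pacemaker channel Hcn2 fell by 0.72 log2. Calcium handling genes split, with 3 of 25 higher and 7 lower (3 and 7 adjusted over the list alone), Ryr2 at 0.49 and Sri at -0.48 log2. Their median of -0.05 log2, with camera pointing up (adjusted p = 0.59), turned to 0.07 under median-of-ratios scaling and 0.02 under quantile normalization, and was -0.13 without both hearts.

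Of 47 ribosomal protein genes 26 fell and 0 rose (31 and 0 adjusted over the list alone), with a median of -0.23 log2 (adjusted p = 6.19e-05, and adjusted p = 0.291 with an estimated correlation). Rpl10 fell by 0.44 and Rps23 by 0.35, and by 0.22 under median-of-ratios scaling. The list's median was -0.10 under that scaling and -0.15 without OGT_TG replicates 3 and 6. Of 24 p53 and cell death genes 14 fell and 0 rose (16 and 0 adjusted over the list alone), with a median of -0.29 (adjusted p = 0.00371, and adjusted p = 0.214 with an estimated correlation). Bcl2 fell by 1.01 and Casp12, a caspase of the endoplasmic reticulum, by 1.06. Of 25 inflammation genes 14 fell and 0 rose (15 and 0 adjusted over the list alone), C3 by 0.88, with a median of -0.49 (adjusted p = 0.00425, and adjusted p = 0.355 with an estimated correlation), -0.32 without both hearts. Of 13 O-GlcNAc and hexosamine genes 9 fell and 0 rose (10 and 0 adjusted over the list alone), Gfpt2 by 0.61, with a median of -0.28 (adjusted p = 0.00425, and adjusted p = 0.214 with an estimated correlation). Lamp1 fell from 314.9 ± 9.77 to 231.8 ± 6.34 FPKM (SD, n = 6). Other rises were Gpt (1.32), alanine aminotransferase, Aqp4 (1.21), a water channel, Tnnt1 (1.03), slow skeletal troponin T, and Rpl3l (1.24 log2, 0.59 without both hearts), a muscle form of a ribosomal protein. Nupr1, a stress-induced nuclear protein, fell by 1.36 log2, and by 0.77 without both.

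With both hearts left out, 289 genes rose and 2496 fell, 2785 in all, 2379 of them among the 3878. The median difference of all tested genes was -0.11 log2 as deposited. Under median-of-ratios scaling it was 0.00, with 1371 rises and 1497 falls, 2101 genes being shared with the deposited scale. Under quantile normalization there were 1273 rises and 1364 falls.

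The interaction asked whether the OGA transgene acted differently in hearts with and without the OGT transgene. The OGT row itself had an interaction of 2.13 log2. Its higher level in DTG and the title numbers cannot be told apart from an effect of the OGA transgene here. Ankrd1 showed an interaction, at 886.2 ± 242 FPKM in WT, 945.1 ± 133 in OGA_TG, 3823 ± 1401 in OGT_TG and 1140 ± 177 in DTG (SD, n = 6). Its interaction was -1.81 log2 (SE 0.27, adjusted p = 0.00091). Krt18, a keratin, Cpxm2, Nppb and Thbs4 had interactions of -1.98, -1.82, -1.80 and -1.93 log2, the last -1.26 without OGT_TG replicates 3 and 6. Positive interactions included Phkg1 (1.54), the muscle subunit of phosphorylase kinase, Kcnj2 (1.34) and Kcnq1 (0.75 log2), a delayed rectifier potassium channel. Tmprss13, a membrane protease, was at 0.797 ± 0.272 FPKM in WT, 0.329 ± 0.106 in OGA_TG, 0.779 ± 0.407 in OGT_TG and 2.43 ± 0.453 in DTG (adjusted p = 0.00065). Of 12020 genes 877 had an interaction, 217 positive and 660 negative, and 82 reached 1 log2 (19 positive and 63 negative).

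Of 45 matrix genes 13 had a negative interaction and 0 a positive one (21 and 0 adjusted over the list alone), Dcn at -0.79, with a median of -0.77 log2 (adjusted p = 1.78e-08, and adjusted p = 0.374 with an estimated correlation). Of 18 stress genes 7 were negative and 0 positive (11 and 0 adjusted over the list alone), with a median of -0.76 (adjusted p = 0.00028, and adjusted p = 0.372 with an estimated correlation). In complexes II to V 4 of 40 genes were positive and 0 negative (13 and 0 adjusted over the list alone), with a median of 0.29 (adjusted p = 3.74e-16, and adjusted p = 0.289 with an estimated correlation). In complex I 3 of 35 were positive and 0 negative (4 and 0 adjusted over the list alone), with a median of 0.26 (adjusted p = 3.92e-13, and adjusted p = 0.289 with an estimated correlation). Of 33 ion channel genes 5 were positive and 2 negative (10 and 2 adjusted over the list alone), with a median of 0.33 (adjusted p = 1.66e-07, and adjusted p = 0.289 with an estimated correlation). Bcl2 (-1.06), Gfpt2 (-0.71) and Lamp1 (-0.33 log2) also had negative interactions. Leaving out OGT_TG replicates 3 and 6, 557 genes had an interaction, 483 of them among the 877. The medians were then -0.25 for matrix, -0.41 for stress, 0.17 for complexes II to V, 0.12 for complex I and 0.22 log2 for ion channel genes.

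Single hearts moved the interaction count. It was 568 without WT replicate 2, 515 without WT replicate 6, 539 without OGA_TG replicate 5, 1459 without OGT_TG replicate 2, 523 without OGT_TG replicate 3, 564 without DTG replicate 2 and 526 without DTG replicate 3. Under median-of-ratios scaling 325 interactions were positive and 388 negative, and under quantile normalization 303 and 373.

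How far the genes changed in OGT_TG remained changed in DTG was counted next. Of the 4499 genes, 2430 (54.0%) moved back in DTG against OGT_TG, and 1016 (22.6%) were still changed in the same direction in DTG against WT. The genes were chosen on the same OGT_TG and WT hearts that enter these counts. Shared OGT_TG hearts favour moving back, and shared WT hearts favour staying changed. Both held for 161 genes, Scn4b among them, and neither for 1214. Of the 3029 genes higher in OGT_TG, 2030 (67.0%) moved back, among them Ankrd1, Dcn and Bcl2. Of the 1470 lower genes 400 (27.2%) moved back, among them Cpt2 and Ryr2, while 643 (43.7%) were still lower in DTG, among them Hadhb and Kcnip2. Under median-of-ratios scaling 47.8% of higher and 42.3% of lower genes moved back, and 20.8% and 28.3% were still changed. Without OGT_TG replicates 3 and 6, 1304 of 3036 genes (43.0%) moved back and 1256 (41.4%) were still changed. Of 2107 higher genes 1169 (55.5%) then moved back and 618 (29.3%) were still higher, and of 929 lower genes 135 (14.5%) moved back and 638 (68.7%) were still lower. When genes were chosen on one set of 3 OGT_TG and 3 WT hearts and measured on the others, the DTG difference from WT was 45.9% of the OGT_TG difference (median of 48 splits, 26.7% to 74.6%). It was 38.2% for higher genes (22.8% to 76.6%) and 66.2% for lower genes (33.7% to 91.3%), ranges that overlap. Under median-of-ratios scaling it was 47.7% (32.4% to 72.3%) and 56.4% (15.6% to 75.4%) over 44 splits.

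**Figure D4:**
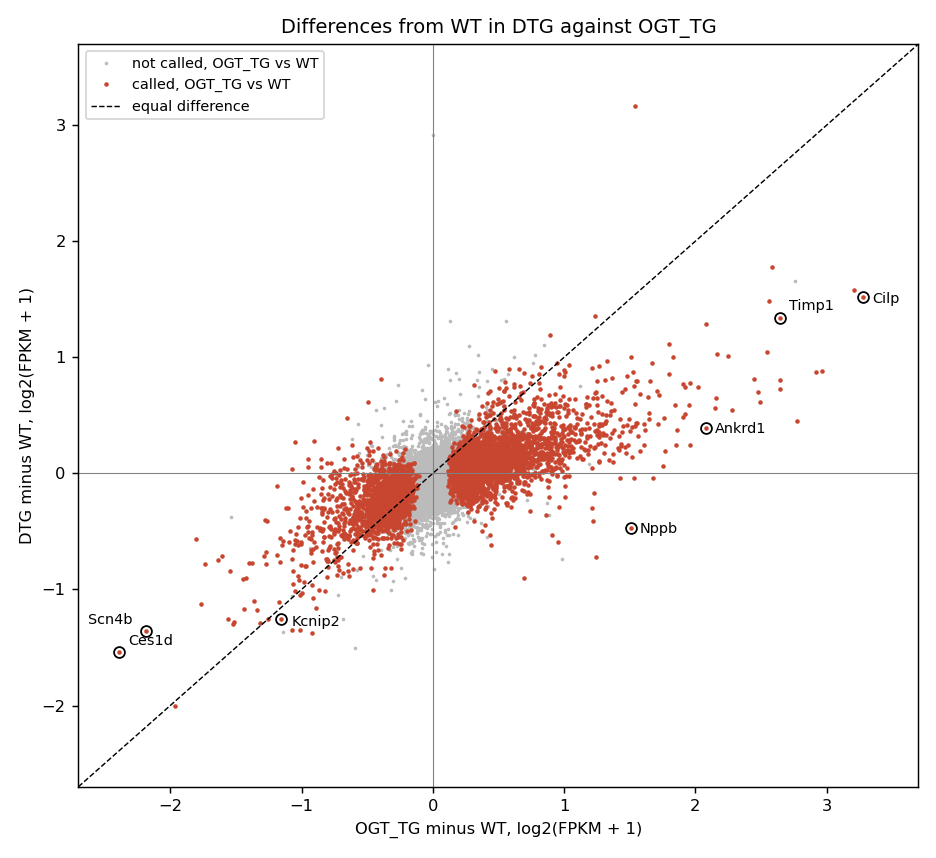
Log2 difference from WT in DTG (vertical) against OGT_TG (horizontal) for each tested gene except the transgene rows, with genes called in OGT_TG in red. Cilp stood at 3.28 in OGT_TG and 1.52 in DTG and Ankrd1 at 2.08 and 0.39, while Kcnip2 stood at -1.15 and -1.25.

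Across genes, which are not independent replicates, the OGT_TG and DTG differences from WT had r = 0.620. These differences share the WT hearts, and unchanged groups set against the same controls gave a mean of 0.455 (-0.296 to 0.926). With the WT hearts split between the differences r was 0.521. Their covariance was 0.0643, against 0.00751 for unchanged groups. Both called 373 genes higher and 643 lower, and 44 genes were called in opposite directions. Independent calls would give 127.5 and 167.8, a reference that leaves out the shared WT hearts. With 3 WT hearts for each difference, a test added after the overlap was seen, both called a median of 107 genes higher and 182 lower over 20 fits, where independent calls would give 23.8 and 29.1. For OGA_TG and OGT_TG r was -0.00492, where unchanged groups gave a mean of 0.477 (-0.405 to 0.93), and -0.0969 with split controls, with a covariance of -0.000314 against 0.00723. Of their called genes 21 went in opposite directions, 2 were higher in both and 2 lower in both. Independent calls would give 1.76 higher and 4.40 lower in both, and the number expected in opposite directions was not computed. With 3 WT hearts for each difference, a median of 3.5 genes went in opposite directions over 20 fits, with 0 higher and 0 lower in both. For OGA_TG and DTG r was 0.323, against a mean of 0.482 (-0.436 to 0.901) for unchanged groups, and 0.159 with split controls. Both called 3 genes higher and 7 lower, where independent calls would give 0.295 and 4.11. The OGA row is among the 3 by the design of the genotypes, and Vmn1r220, present only in hearts with the OGA transgene, is another.

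The single transgenic genotypes were also compared with each other and with DTG. Against OGA_TG, 3997 genes rose and 1335 fell in OGT_TG, 5332 in all, with Ankrd1 at 1.95, Dcn at 1.06 and Hadhb at -0.81 log2. Of 45 matrix genes 44 rose and 0 fell (44 and 0 adjusted over the list alone), with a median of 1.26 (adjusted p = 2.05e-11, and adjusted p = 0.314 with an estimated correlation), 0.74 without OGT_TG replicates 3 and 6, and of 27 fatty acid oxidation genes 25 fell and 0 rose (25 and 0 adjusted over the list alone). Against OGA_TG, 1001 genes rose and 1174 fell in DTG, 2175 in all, with Hadhb at -0.77, Atp2a2 at -0.59 and Mgea5 at 0.93 log2. Of 27 fatty acid oxidation genes 16 fell and 0 rose (16 and 0 adjusted over the list alone), with a median of -0.28, and of 25 interferon genes 11 rose and 0 fell (14 and 0 adjusted over the list alone). Without OGT_TG replicates 3 and 6, 3320 genes rose and 930 fell in OGT_TG against OGA_TG. Under median-of-ratios scaling that split was 2492 and 2455 and under quantile normalization 2202 and 2586. For DTG against OGA_TG an equal sum of FPKM gave 1226 rises and 902 falls.

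Each genotype's difference from WT was tested for a difference between the sexes. In WT, OGT_TG and OGA_TG each title number held a single sex, so sex cannot be told apart there from what the number stands for. With limma, 0 of 12020 genes passed for OGT_TG, OGA_TG or DTG, and 196, 370 and 173 had an unadjusted p under 0.05, where 601 would be expected. Fitted on the compared groups alone, 0 genes passed in each case, with 135, 697 and 227 at an unadjusted p under 0.05. Sex itself, over all genotypes, changed 32 genes, among them the complement gene C7, higher in males by 1.71 log2, and Xist and Ddx3y.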

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

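The test for a mislabelled sample, the comparison of marker medians with the other OGT_TG hearts, the binomial p on chromosome 13 and the 3 tests of the OGT row in DTG were chosen after the results they measure were seen. For each gene named in the text for a main comparison, the gap between the highest or lowest heart and its nearest neighbour was set against the range of the 6 hearts, in the genotypes of that comparison. The sum of FPKM, number of rows, relative depth and share of abundant rows were treated alike, while Ddx3y, Xist, C7, D830015G02Rik and Prlr were not tested. Of 274 such groups, 12 passed Dixon's critical value, where chance gives 13.7. Hearts that stand apart together can go unflagged by this rule, as OGT_TG replicates 3 and 6 did for Nppa. A count near chance therefore does not show that no heart stood apart.

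Among WT hearts, replicate 1 was lowest for Wisp2, at 1.45 FPKM against 3.28 to 4.24 in the others, and highest for Pln (3957 FPKM against 3006 to 3297) and Canx (129.95 FPKM against 104.1 to 113.1). WT replicate 3 was highest for Adamtsl2 (5.84 FPKM against 2.17 to 3.04), Pdia6 (70.3 against 49.4 to 53.1), Hyou1 (19.6 against 13.8 to 15.7) and Irf7 (11.9 against 4.94 to 6.61). WT replicate 6 was highest for Acadvl, at 623.1 FPKM against 542.1 to 568.1. Among DTG hearts, replicate 2 was highest for Adamtsl2 (22.7 FPKM against 8.53 to 13.8) and lowest for Hadhb (739.2 against 816.1 to 852.3). DTG replicate 6 was lowest for Gpt (13.8 FPKM against 18.6 to 20.1). Among OGT_TG hearts, which lack the OGA transgene, replicate 2 had 0.0125 FPKM on the OGA row and the others 0.

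OGT_TG replicates 3 and 6 stood apart from the other 4 OGT_TG hearts in natriuretic peptide, matrix and metabolic genes. A wrong label is argued against by the OGT row, at least 714.7 FPKM in both hearts, where no heart without the transgene exceeded 3.44. More atrial tissue would raise atrial markers, but over the 10 markers other than Nppa the median difference from WT was -0.60 log2 in replicate 3 and -1.01 in replicate 6. A lower share of cardiomyocytes stays open, since fibroblast and endothelial medians against WT lay 1.37 and 0.75 log2 apart in replicates 3 and 6, but also 0.55 to 0.79 apart in the other OGT_TG hearts, so the bound of 0.5 set for this test did not single out these hearts. A candidate explanation is a more advanced disease state in these hearts, which no label of the design allows to be tested.

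The OGT row was higher in DTG than in OGT_TG by 1.54 log2. The deposited scale is argued against as the whole cause, since the difference was at least 1.45 log2 under 3 other scalings. Reads shared with mouse Ogt are argued against too, since the Ogt row reached at most 35.9 FPKM in these hearts, 1.23% of the difference of 2904 FPKM in the OGT row. Without OGT_TG replicates 3 and 6, whose OGT row was lowest, the difference was 1.12 log2 (limma adjusted p = 0.0049). Loss of OGT_TG mice with high expression before sampling may be a biological explanation and was not tested.

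Vmn1r220 was present in OGA_TG and DTG hearts and listed at 0 in WT and OGT_TG hearts. A change of neighbouring genes stays open. Of the 16 other tested genes within 2 Mb, 0 were called in the same direction in OGA_TG against WT and DTG against OGT_TG. Only 22 other genes among all tested rows were called alike in both comparisons. A count of 0 near Vmn1r220 is therefore likely without a local change and cannot exclude a small one. Neighbours below the expression minimum were not tested. A strain variant carried along with the transgene stays open, since 0% of the 21 genes with a position that changed alike lay on chromosome 13, where 0.75 would be expected from its 3.57% of tested genes (binomial p = 0.0925 for as few at 3 times that share). Reads from the transgene assigned to this gene cannot be told apart from expression of the gene itself, because both follow the OGA transgene. The log2 ratio of Vmn1r220 to the OGA row was lower in DTG than in OGA_TG by -0.34 (SE 0.12, exact permutation p = 0.0195).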

How the results depend on the processing

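The setting without OGT_TG replicates 3 and 6 was chosen after their values were seen. Counts of changed genes stayed within 1.5 times the values in the report under a pseudocount of 0.1, no filter, a stricter filter, no sex term, robust moderation, an equal sum of FPKM and median-of-ratios scaling. The exceptions among other settings follow, and where no reason is given the cause was not tested. For the low count in OGA_TG, quantile normalization gave 24.

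At an adjusted p under 0.01, a stricter threshold by construction, counts were 2844 (OGT_TG against WT), 21 (OGA_TG against WT), 911 (DTG against WT), 2176 (DTG against OGT_TG), 1117 (DTG against OGA_TG) and 146 (interaction). With a minimum of 0.5 log2 they were 1440, 21, 411, 907 and 511 in the same order up to DTG against OGA_TG, 1822 for OGT_TG against OGA_TG and 486 for the interaction. With library weights they were 319 for OGA_TG against WT, 3553 for DTG against WT, 3874 for DTG against OGA_TG and 2085 for the interaction. Fitted on the compared groups alone, OGA_TG against WT gave 81 and DTG against OGT_TG 2463.

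With fewer hearts in single-sex fits, males gave 2061 genes for OGT_TG against WT and females 1409. OGA_TG against WT gave 6 and 4, DTG against WT 195 and 250, DTG against OGT_TG 1420 and 419, DTG against OGA_TG 360 and 658, OGT_TG against OGA_TG 3145 and 2804, and the interaction 1 and 0. With 1 heart left out, OGA_TG against WT ranged from 23 without OGA_TG replicate 5 to 34 without WT replicate 1, and was 28 without WT replicate 5 and 25 without OGA_TG replicate 2. The interaction ranged from 515 without WT replicate 6 to 1459 without OGT_TG replicate 2, and was 568 without WT replicate 2, 539 without OGA_TG replicate 5, 523 without OGT_TG replicate 3, 564 without DTG replicate 2 and 526 without DTG replicate 3. Without both OGT_TG replicates 3 and 6 it was 557, and 1304 genes changed in OGT_TG moved back in DTG, against 2430 with all hearts and 1251 at an adjusted p under 0.01.

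With the title number as a replicate block, OGT_TG against WT gave 4207 genes, 3899 of them among the 4499. Residuals of the 10 same-number pairs of a WT and an OGT_TG heart, all of the same sex, had a median r of 0.0902 (-0.141 to 0.227). Other pairs of the same sex had a median of -0.224, and all other pairs -0.0301. Because r exceeded 0.1 in 5 of the 10 pairs and not in each, the numbers were not used to pair hearts. That rule ignores the negative median of other same-sex pairs, above which the median of same-number pairs lay. Likeness of hearts that share a number therefore cannot be excluded, and the main p-values treat hearts as independent. Tnnc1, slow skeletal and cardiac troponin C, turned direction in DTG against OGT_TG, from 0.21 log2 to -0.10 under quantile normalization (adjusted p = 0.229), and the cause was not tested. Depth of about 11.3 to 17.6 M fragments limits what can be said of genes under 1 FPKM.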

Other observations

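In this part, D830015G02Rik, Prlr, the adipocyte medians per heart and the Ddx3y value were picked after their values were seen, and so was the count of genes that changed alike with and without the OGT transgene.

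Genes of the unfolded protein response and chaperones split in DTG hearts against WT, with 5 of 30 higher and 11 lower (5 and 13 adjusted over the list alone) and a median of -0.11 log2 (camera adjusted p = 0.333). Pdia6, a protein disulfide isomerase, Canx, a chaperone of glycoproteins, and Hyou1, an endoplasmic reticulum chaperone, fell by 0.49, 0.46 and 0.42 log2, while Hspb6, a small heat shock protein, rose by 0.41 and Ddit3, a stress transcription factor, by 0.53. Ucp2, a mitochondrial carrier, rose by 0.87 log2. Of 9 adipocyte markers 2 rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 0.81 log2 (adjusted p = 4.76e-05, and adjusted p = 0.216 with an estimated correlation), Cidea, a lipid droplet protein, by 0.58. Per heart, the median of these markers against the WT mean was 1.45 and 1.77 in DTG replicates 3 and 4, 0.09 in replicate 1 and 0.49 to 0.77 in the others, and 1.12 in OGT_TG replicate 4. The uncharacterized transcript D830015G02Rik averaged 158.4 ± 30.0 FPKM in WT, 274.7 ± 22.2 in OGA_TG, 496.8 ± 211.5 in OGT_TG and 1427 ± 235.2 in DTG (SD, n = 6), and its differences from WT were 0.81 log2 in OGA_TG (adjusted p = 0.12), 1.54 in OGT_TG and 3.16 in DTG.

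Apart from Vmn1r220 and the OGA row, 22 genes changed in the same direction in OGA_TG against WT and in DTG against OGT_TG, and all 22 fell, where independent calls would give 9.81 falls. Among the 22 were Tac1 (-1.08 and -1.01 log2), Igsf1 (-0.84 and -0.96), Camk2b (-0.75 and -0.70), Cds1 (-0.69 and -0.84) and Prlr (-0.51 and -0.57), the prolactin receptor. The count of 22 was 12 with an equal sum of FPKM, 8 under median-of-ratios scaling and 7 under quantile normalization, where independent calls would give 5.49, 2.24 and 1.70. Genes higher in both then numbered 1, 2 and 1.

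Ddx3y, a Y chromosome gene, stood at 0.514 FPKM in DTG replicate 6, a female with Xist at 22.9 FPKM. The other female hearts were between 0 and 0.0173 FPKM.

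Counts of genes between groups were compared with counts from 100 splits of the same hearts into groups of the same size, the real split included. The real split alone reached its count, 1 of 100, for OGT_TG against WT (4499, highest other 2684), OGA_TG against WT (43, highest other 0), DTG against WT (1878, highest other 648), DTG against OGT_TG (3878, highest other 1694), DTG against OGA_TG (2175, highest other 136) and OGT_TG against OGA_TG (5332, highest other 3049). A random grouping of these hearts is therefore an unlikely source of these counts, though only 100 of 462 possible splits were drawn. Such splits cannot tell genotype from the title number for OGA_TG and DTG. For the interaction, residuals of a fit without it were reassigned among hearts, and 2 of 100 assignments reached 877, the real one and another at 1496. For a different effect by sex the real count was 0 with limma in OGT_TG, OGA_TG and DTG, with 196, 370 and 173 genes at an unadjusted p under 0.05, so all 100 assignments of sex within genotype reached it by construction. The highest others were 3153, 1 and 16.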
